A study of Mus musculus with 8 samples.

How the data were processed

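The material was whole kidney from C57BL/6 mice, with 6 samples titled Control and 2 titled UUO, sequenced as 10x Genomics Chromium single-cell 3′ libraries, per the labels' protocols. Groups and sample numbers were taken from the titles. Per the submitters' processing notes, Cell Ranger 6.0.1, Seurat 4.0.1 and the genome build mm10 were used, and the role and settings of each are not given in the sources used here. How cells were filtered, classes called and the embedding computed is not given in those sources either. Genes per cell ran from 298 to 2998 and mitochondrial percentages up to 50.0, so cells beyond these values are not in the table.

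The deposited table holds 1 row per cell with 3 measures. UMIs per cell are counts of molecules summed over genes and not normalized, per the file headers, and genes detected per cell are likewise whole counts made by the authors. The mitochondrial share is a percent of each cell's UMIs, per the file headers, and multiplying it by the UMIs gave a whole number of molecules in 100% of cells (tolerance 0.001). The authors' class name and sample name of each cell were used as given. A further deposited table gives UMAP coordinates, a score with no unit, for 25200 cells, which are all cells outside the class PT. All per-sample columns were used (0 left out). Gene-level counts and the bulk data the series' design text speaks of are not analysed here, so no class was checked against its marker genes, and doublets were treated only as the authors left them.

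Classes were placed in compartments by name: 10 in tubular epithelium, 1 (podocytes) in other epithelium, Endo and GEC in endothelium, 6 in myeloid and 9 in lymphoid, the last 2 together making immune. No class had a stromal name, so fibroblasts could not be compared. Prolif Ly was taken as lymphoid. The text names every compartment, every class past an adjusted p of 0.05 in the comparison of shares of all cells, every basophil, T helper, CD4 or other T cell class, and every proximal tubule class. This rule, the tests and the first set of alternatives were fixed before the data were examined.

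The value tested was the share of a sample's cells, since cells are not replicates. Compartment shares were compared on the log2 odds scale, log2((n + 0.5)/(N - n + 0.5)), by a two-sided exact permutation test on the difference of group means. Class shares of all cells, of immune cells and of tubular cells were fitted with limma 3.58.1 in R 4.3.3 on the same scale, with Benjamini-Hochberg adjustment over classes and a threshold of 0.05. The variance prior took over fully in the fits of all cells and of tubular cells, so every class there has the same standard error. Their 140 and 50 degrees of freedom count classes as independent, although shares sum to a whole and can move together. Those intervals and p-values therefore do not measure a class's own spread and may be too narrow or too low. Classes of under 20 cells over all samples were to be left out, and there were 0. Sample medians of UMIs, genes (log2) and mitochondrial percentage were compared by the exact test over all cells and by limma per class, for the 19 classes with at least 20 cells in at least 2 samples of each group. Embedding positions were compared by the exact test on the distance between group means of sample medians. A comparison of cell cycle phases was planned and could not be computed from the columns used here, and no other annotation was held for the planned comparison of annotations.

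The planned design took all 8 samples as separate, with 28 ways of choosing 2 of them. The class numbers of Controls 3 and 4 did not differ at a chi-square p under 0.05, though they came close to it. Their cells were therefore pooled and counted as 1 sample, a step taken after seeing the data, and the fit with 8 separate samples is given as an alternative. No 2 cells with the same barcode in different samples had the same UMIs and genes. Depth sets the precision of each share: a sample total of 2263 to 18393 cells and of 4375942 to 56755823 UMIs lay behind each sample, and the exact (Clopper-Pearson) 95% intervals printed for single samples cover counting error only. A class with 0 cells in the smallest sample could still make up 0.133% of it.

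Alternatives fixed beforehand were the arcsine square root scale, edgeR 4.0.16 quasi-likelihood tests on cell numbers with sample totals or TMM scaling, centred log-ratios, an offset of 1 cell, no minimum class size, a minimum of 1000 UMIs, exact permutation per class, sample weights, the sample number as a block, and leaving out each sample. Added after seeing the data were leaving out immune cells at or above 10% mitochondrial UMIs, the libraries over 10000 cells alone, leaving out Controls 3 and 4 or Controls 5 and 6, and tubular cells outside PT as the denominator. The functions were tested on simulated data built from the Control means and spreads of the log2 odds at the real sample sizes, 200 data sets per comparison. The odds were rescaled to sum to a whole, which makes PT a larger share than in the data. Classes varied independently there. For shares of all cells, 50.1% of classes changed by 3 log2 units were called, 16.8% of those changed by 2, 6.80% of those changed by 1 and 4.90% of unchanged classes. For immune cells these figures were 51.7%, 21.8%, 5.40% and 3.60%, and for tubular cells 75.9%, 47.2%, 14.4% and 8.90%. Classes given no change of their own still shift there, because shares sum to a whole, and strongly so where PT is the class changed. The figures for unchanged classes are therefore not plain error rates. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.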

Results

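Single-cell RNA sequencing of whole mouse kidney was compared between 6 Control samples and 2 samples taken after unilateral ureteric obstruction (UUO), in which 1 ureter is tied off so that urine backs up and injures the kidney. UUO is widely used to produce tubular injury, inflammation and fibrosis. The mice were C57BL/6 animals of 7 weeks, and obstructed animals were killed on day 7 after ligation. The treatment text is the same for every sample, so Control samples were told apart by their titles and disease label, and what was done to those animals is not given in the sources used here. The data comprised 77393 cells, 46070 from Control and 31323 from UUO kidneys, each assigned by the authors to 1 of 28 classes. Control samples 1 to 6 held 3599, 6433, 2263, 3950, 16168, 13657 cells, and UUO samples 1 and 2 held 18393 and 12930. Median UMIs (unique transcript molecules) per cell lay between 1292 and 2944 in the Control samples and were 2496 and 2584 in the UUO samples. The 4 libraries over 10000 cells, Controls 5 and 6 and both UUO samples, gave a comparison at similar size, and the 4 smaller libraries were Control samples only.

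Controls 3 and 4 were counted as 1 sample. A chi-square test on their numbers of cells per class gave p = 0.0509, only just above the cut-off of 0.05 used for pooling. The other 14 pairs of Control samples differed, with p of at most 4.09e-41. Controls 3 and 4 shared only 10 cell barcodes, so they were different cells and not a copied file, and the labels do not say whether they came from 1 kidney. Pooled, they left n = 5 for Control and n = 2 for UUO, 21 ways of choosing the UUO samples and a smallest possible exact p of 0.0476. No label says that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

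The broad make-up of the kidney was compared first, because obstruction is known to bring leukocytes into the tissue. Immune cells made up 23.1% ± 7.98 (SD, n = 2) of the cells in UUO and 7.16% ± 3.42 (SD, n = 5) in Control, a ratio of 3.22. The samples did not overlap: UUO samples 1 and 2 held 17.4% (16.9 to 18.0) and 28.7% (27.9 to 29.5) immune cells (exact 95% binomial intervals, counting error only), and the highest Control sample as counted held 12.7%. Most of the difference was lymphoid, at 18.6% ± 6.50 in UUO against 4.96% ± 3.47 in Control, and myeloid cells were 4.47% ± 1.48 in UUO against 2.20% ± 0.736 in Control. Endothelial cells were 0.741% ± 0.571 in UUO against 3.41% ± 1.40 in Control, tubular epithelium 76.1% ± 8.62 in UUO against 89.2% ± 4.45 in Control, and podocytes, which filter plasma in the glomerulus and were the only other epithelial class, 0.0848% ± 0.0661 in UUO against 0.190% ± 0.107 in Control.

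On the log2 odds scale the UUO minus Control differences were 2.03 for immune, 2.30 for lymphoid, 1.07 for myeloid, -2.37 for endothelium, -1.42 for tubular epithelium and -1.24 for podocytes. Immune, lymphoid, endothelial and tubular shares each reached the smallest two-sided exact permutation p of 0.0476, and the Benjamini-Hochberg value over the 6 compartments was 0.0714 for each, which does not pass 0.05. It could pass only if all 6 compartments reached the smallest p, so not passing is no evidence against a difference. The exact adjusted p was 0.114 for myeloid cells and 0.238 for podocytes. With limma in place of the permutation test, the immune, lymphoid, endothelial and tubular differences passed an adjusted p of 0.05. Among the libraries over 10000 cells alone the log2 odds differences were 2.40 for immune, 2.77 for lymphoid, 1.10 for myeloid, -1.63 for endothelial and -1.92 for tubular cells, where the exact permutation test of 2 samples against 2 cannot go below p of 0.333.

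**Figure D1:**
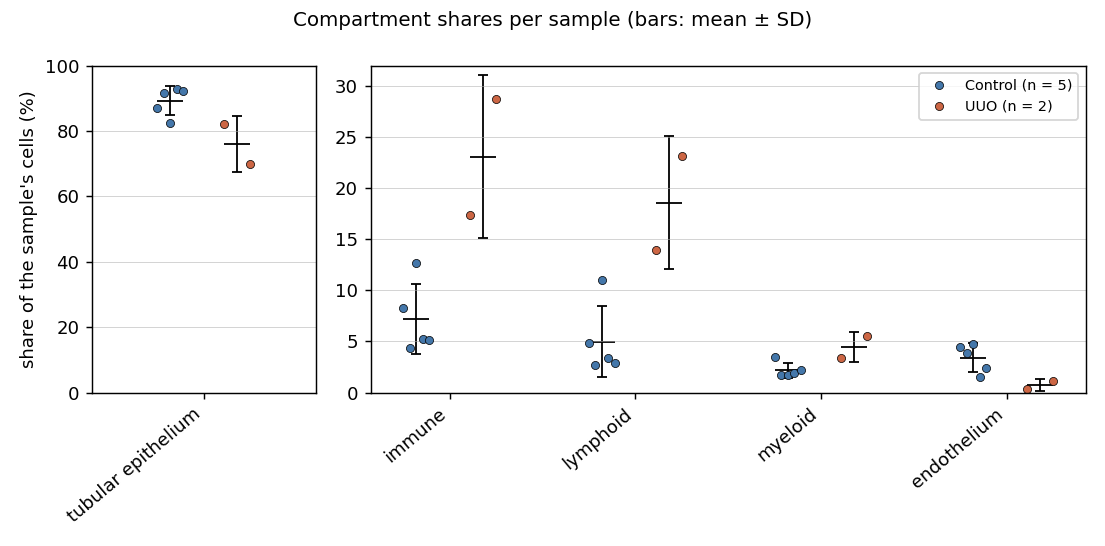
Share of each sample's cells (y axis, percent) in the tubular epithelium (left) and in the immune, lymphoid, myeloid and endothelial compartments (right) for 5 Control and 2 UUO samples as counted; points are samples and bars the mean ± SD. The UUO samples hold 17.4% and 28.7% immune cells, above the highest Control sample at 12.7%, and fewer endothelial cells than every Control sample.

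Of the 28 classes, limma called 6 higher and 8 lower as a share of all cells in UUO, at an adjusted p under 0.05. Basophils, rare granulocytes named in the series title, rose from 0.0484% ± 0.0389 (SD, n = 5) to 0.344% ± 0.225 (SD, n = 2) of the cells, a log2 odds difference of 2.74 (95% interval 1.08 to 4.41). Limma intervals and p-values for shares of all cells use a variance shared by all classes. These shares rest on 21 basophils in the Control and 99 in the UUO samples. Th17 cells, the interleukin-17-producing T helper class also named in the title, rose from 0.325% ± 0.271 to 2.34% ± 0.580, by 3.10 on the log2 odds scale (1.43 to 4.76). CD4 T cells rose from 1.01% ± 0.337 to 5.66% ± 0.761 and CD8 effector cells from 0.320% ± 0.254 to 2.05% ± 1.24.

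Regulatory T cells (Treg), which restrain immune responses, were 2.43% ± 0.925 in UUO against 0.715% ± 1.12 in Control, and CD8 T cells 1.95% ± 0.928 in UUO against 0.479% ± 0.671 in Control. Both rose in the limma fit, by 2.83 and 2.76, but the pooled Controls 3 and 4 held 2.72% and 1.67%, inside the UUO range, and the exact p was 0.190 and 0.0952. NKT cells, at 1.35% ± 0.713 in UUO against 0.596% ± 0.608 in Control, did not pass (log2 odds difference 1.51, limma adjusted p 0.118). That rested on the pooled Controls 3 and 4 too, which held 1.67% NKT against 0.187% to 0.402% in the other Control samples. Without them limma called NKT (1.99), NK (2.28) and Neutro (1.76) higher as well. Of the remaining 8 immune classes, none passed with all samples. Neutrophils, NK cells and monocytes had the highest differences among them, 1.78, 1.77 and 1.23 (limma adjusted p 0.0623, 0.0623 and 0.207), and macrophages had -0.57 (adjusted p 0.550). These immune classes outside the naming rule were chosen after their values were seen.

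The 8 classes called lower were DCT, CNT, CD PC, B-IC, Trans IC, ALOH, Endo and GEC. Distal convoluted tubule (DCT) cells, which reabsorb sodium chloride, fell from 9.43% ± 2.72 to 1.35% ± 1.16, and connecting tubule (CNT) cells from 4.30% ± 1.03 to 0.460% ± 0.466. Principal cells of the collecting duct (CD PC), which take up water and sodium, fell from 2.63% ± 0.748 to 0.304% ± 0.292. The 2 endothelial classes fell from 0.867% ± 0.632 to 0.198% ± 0.157 for Endo and from 2.55% ± 1.07 to 0.543% ± 0.414 for GEC. The groups overlapped in Endo, where UUO 2 held 0.309% and Control 5 held 0.167%. The log2 odds differences of the 8 classes lay between -3.75 for CNT and -1.99 for Endo. Proximal tubule (PT) cells, which reabsorb most of the filtrate, were 70.9% ± 11.9 in UUO against 61.5% ± 11.4 in Control, and proliferating proximal tubule (Prolif PT) cells 0.470% ± 0.205 in UUO against 1.01% ± 1.27 in Control. Neither passed (log2 odds differences 0.63 and -0.56, limma adjusted p 0.550 and 0.550), nor did the class the authors named Profibrotic Tubules, at 0.682% ± 0.0193 in UUO against 0.593% ± 0.283 in Control (adjusted p 0.702). The Control mean of Prolif PT rested on Control 5, at 3.27% against 0.290% to 0.513% in the others, and without it the difference had the other sign (0.03). For PT the difference ran from 0.034 to 1.23 when each sample was left out in turn.

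Limma adjusted p over the 28 classes was 0.00441 for Baso, 0.00187 for Th17, 0.00628 for CD4 T, 0.00429 for CD8 effector, 0.00429 for Treg and 0.00441 for CD8 T. It lay between 0.000478 for CNT and 0.0395 for Endo among the classes that fell. The exact permutation p was 0.0476 in 11 of the 14 classes and 0.143 for Endo. After Benjamini-Hochberg adjustment the exact p-values passed for 0 classes (lowest 0.111, 12 classes under 0.05 unadjusted). They could pass only if nearly all 28 classes reached 0.0476, so this is no evidence against a difference. The edgeR quasi-likelihood test on cell numbers called 4 classes higher and 5 lower. Among the libraries over 10000 cells alone limma called 7 higher and 5 lower, with 3.24 for Baso, 3.47 for Th17, 2.72 for CD4 T and -3.49 for CNT. The count rests on both UUO samples: without UUO 1 only Baso, Th17 and CD8 effector were called higher and no class lower, and without UUO 2 only Th17 and CD4 T were called higher, with 9 lower. Without UUO 1 the differences shrank to -2.46 for CNT, -2.34 for CD PC, -1.72 for Trans IC, -1.53 for GEC and -1.45 for ALOH. Endo was not called without Control 1 (-1.65), Control 2 (-1.72), Control 6 (-2.09) or UUO 1 (-1.08), and without Control 5 Neutro (1.97) and A-IC (-1.97) were called too.

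**Figure D2:**
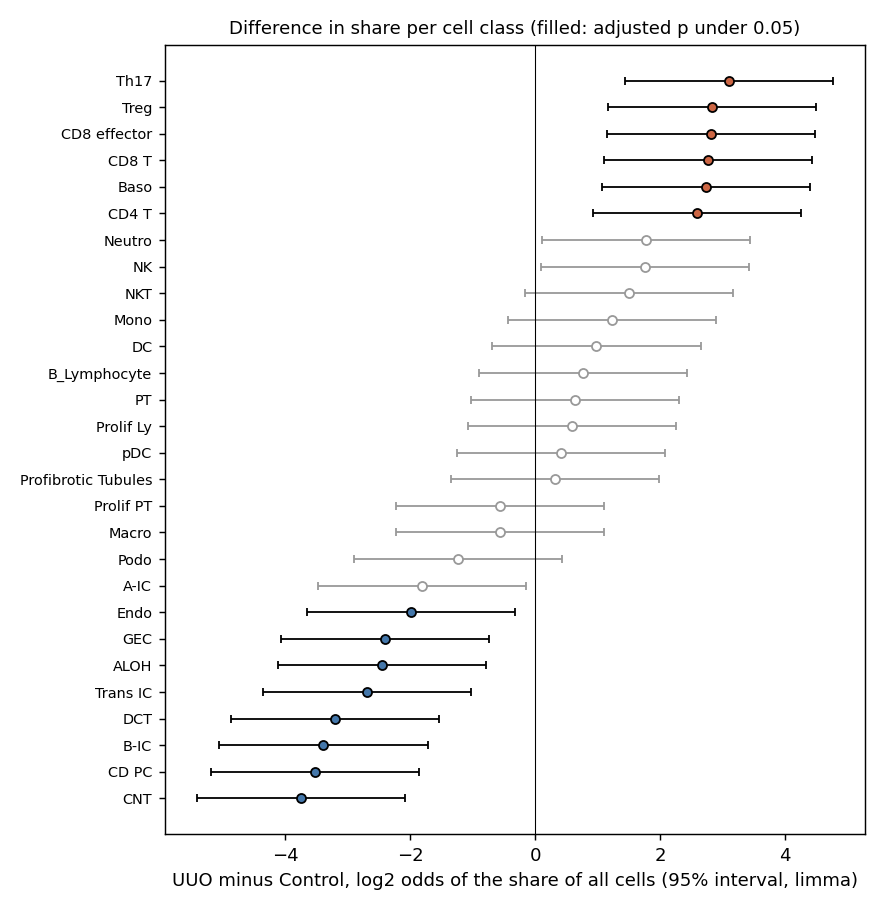
UUO minus Control difference in the log2 odds of each class's share of all cells (x axis) for the 28 classes (y axis), with 95% intervals from limma over 5 Control and 2 UUO samples, using a variance shared by all classes. Filled points passed an adjusted p of 0.05: 6 classes lie to the right of 0, with Th17 farthest at 3.10, and 8 to the left, with CNT farthest at -3.75.

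Shares of all cells fall in every other class when 1 class expands, so tubule classes were also taken as shares of tubular cells alone. PT cells rose from 68.6% ± 9.99 (SD, n = 5) to 92.9% ± 5.08 (SD, n = 2) of the tubular cells, and 6 classes of the loop, distal tubule and collecting duct fell. DCT fell from 10.6% ± 3.33 to 1.88% ± 1.74, ascending loop of Henle (ALOH) cells from 6.13% ± 3.80 to 1.54% ± 1.41 (a log2 difference of the other sign, 0.11, with TMM scaling), and CNT from 4.87% ± 1.43 to 0.643% ± 0.684. CD PC fell from 2.94% ± 0.831 to 0.424% ± 0.431, base-secreting B-IC from 1.87% ± 0.607 to 0.231% ± 0.158, and Trans IC from 1.33% ± 0.845 to 0.276% ± 0.250. Acid-secreting A-IC were 0.632% ± 0.482 in UUO against 1.88% ± 1.47 in Control and did not pass (limma adjusted p 0.0584). Prolif PT cells were 0.606% ± 0.20 in UUO against 1.10% ± 1.36 in Control (adjusted p 0.678) and Profibrotic Tubules 0.904% ± 0.128 in UUO against 0.667% ± 0.325 in Control (adjusted p 0.527). Control 5 held 3.52% Prolif PT against 0.351% to 0.560% in the other Control samples. The Prolif PT difference was -0.32 with it and of the other sign without it (0.25), with TMM scaling (1.90) or with centred log-ratios (1.5). A-IC and Profibrotic Tubules were chosen after their values were seen.

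In log2 odds, PT rose by 2.74 (95% interval 1.19 to 4.29, limma adjusted p 0.00171), and CNT fell by 3.53 (-5.08 to -1.97, adjusted p 0.000331). The other 5 falling classes lay between -3.29 for CD PC and -2.23 for ALOH, with adjusted p of at most 0.00832. The exact p was 0.0476 for PT, DCT, CNT, CD PC, B-IC and Trans IC and 0.0952 for ALOH, and its adjusted value was at least 0.0794. Passing 0.05 would have needed every tubule class at 0.0476. The split of 1 higher and 6 lower depended on the scale: TMM scaling in edgeR gave 2 higher (PT and Profibrotic Tubules) and 1 lower (CNT), centred log-ratios gave 2 higher and 4 lower, and edgeR with sample totals gave 0 higher and 5 lower. With PT out of the denominator, an alternative chosen after the data were seen, limma gave 1 higher (Profibrotic Tubules) and 2 lower (CNT and B-IC), and ALOH had the other sign (0.15). Without UUO 1, in which only 3.54% of tubular cells lay outside PT against 10.7% in UUO 2, no tubule class passed (limma, 5 at an unadjusted p under 0.05). The differences there were 1.89 for PT, -2.12 for CNT, -1.99 for CD PC, -1.83 for DCT, -1.38 for Trans IC and -1.10 for ALOH. Without UUO 2 they were 3.60 for PT, -4.94 for CNT and -3.35 for ALOH. A-IC was called lower without UUO 2 (-2.45) or Control 5 (-1.75). The libraries over 10000 cells gave 0 higher and 4 lower, with PT at 2.40.

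**Figure D3:**
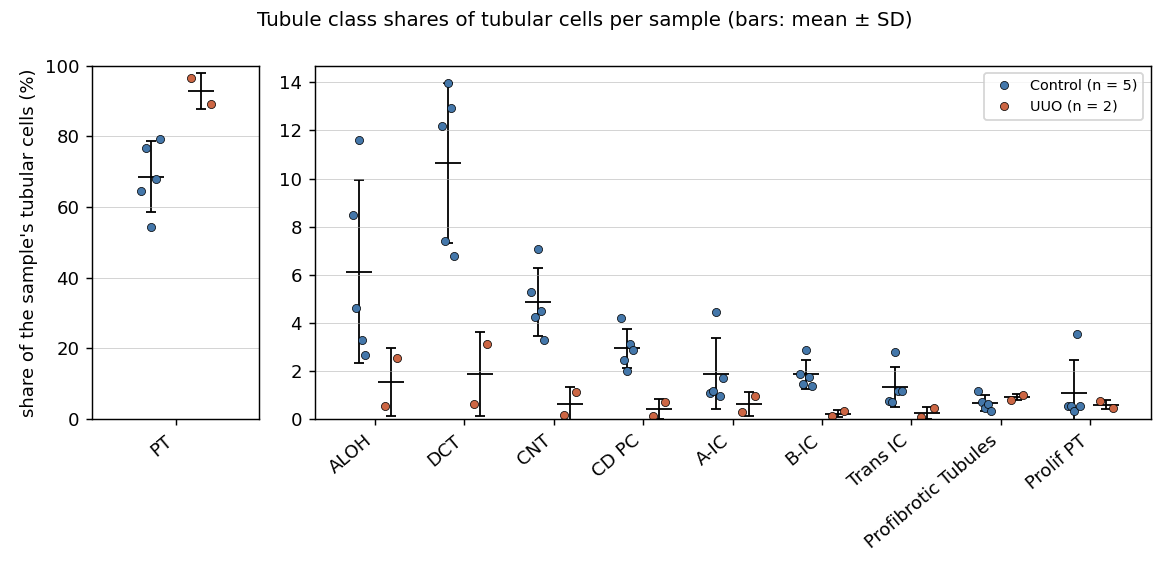
Share of each sample's tubular cells (y axis, percent) in the PT class (left) and in the other 9 tubule classes (right) for 5 Control and 2 UUO samples as counted; points are samples and bars the mean ± SD, drawn down to 0. PT makes up 89.3% and 96.5% of tubular cells in the UUO samples against at most 79.3% in a Control sample, and DCT, CNT, CD PC and B-IC lie below every Control sample in both.

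Within the immune compartment, where the number of tubular cells recovered has no effect, no class of the 15 passed an adjusted p of 0.05 with limma or with edgeR. Th17 cells made up 10.3% ± 1.05 (SD, n = 2) of immune cells in UUO and 4.22% ± 1.46 (SD, n = 5) in Control, and CD4 T cells 25.5% ± 5.53 and 15.3% ± 4.39. Basophils were 1.41% ± 0.488 in UUO against 0.655% ± 0.340 in Control, Treg 10.5% ± 0.386 in UUO against 7.19% ± 8.06 in Control and NKT cells 5.67% ± 1.13 in UUO against 7.23% ± 3.61 in Control. CD8 effector cells were 8.47% ± 2.45 in UUO against 4.08% ± 1.14 in Control and CD8 T cells 8.25% ± 1.17 in UUO against 5.09% ± 4.58 in Control. Macrophages, phagocytes that reside in the kidney and also enter it from blood, were 1.58% ± 0.286 in UUO against 10.6% ± 8.85 in Control.

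The log2 odds differences within immune cells were 1.41 for Th17 (95% interval 0.07 to 2.74, limma adjusted p 0.301, higher in both UUO samples than in every Control sample), 0.99 for Baso (0.390), 0.95 for CD4 T (0.390), 1.10 for Treg (0.390), 1.03 for CD8 T (0.390), 1.10 for CD8 effector (0.352) and -0.29 for NKT (0.770). At an unadjusted p under 0.05, limma gave 1 class higher (Th17) and 1 lower (Macro, -2.46, adjusted p 0.240), and edgeR with sample totals gave Th17 and Macro. The exact permutation p was 0.0476 for 2 classes, Th17 and CD8 effector, and passed for 0 after adjustment, where passing would have needed every immune class at 0.0476. For CD8 effector the groups were apart only with Controls 3 and 4 pooled, at 5.97%. Control 4 alone held 7.22%, above UUO 1 at 6.74%. The count depended on Controls 3 and 4, in which Treg were 21.5% of immune cells. Without them limma called Th17, Treg, CD8 T and CD8 effector higher and Macro lower, with 1.57 for Th17 and 1.68 for Treg. The libraries over 10000 cells alone gave Th17, Treg, CD8 T and CD8 effector higher and Macro and Neutro lower, with Baso at 1.15. In Controls 5 and 6, 156 of 201 and 47 of 147 neutrophils had at least 10% mitochondrial UMIs. In UUO 1 and 2 these were 43 of 400 and 50 of 366. The lower Neutro share in these libraries may therefore rest on such cells, and it was not fitted without them.

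**Figure D4:**
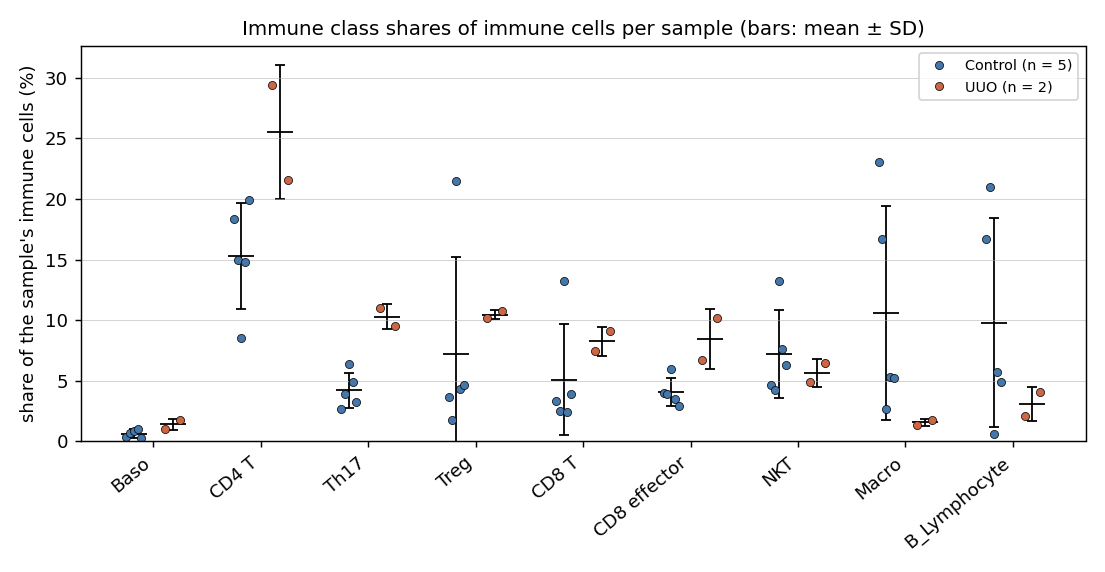
Share of each sample's immune cells (y axis, percent) in 9 immune classes (x axis) for 5 Control and 2 UUO samples as counted; points are samples and bars the mean ± SD, drawn down to 0. Th17 cells make up 9.56% and 11.05% of immune cells in UUO against at most 6.35% in a Control sample, and 1 Control point, the pooled Controls 3 and 4, lies above both UUO samples in Treg and CD8 T.

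UMIs and genes detected per cell were compared between the groups by class. These are raw counts, which mix the depth of a library with the transcript content of its cells. Over all cells the UUO to Control ratio of UMIs was 1.48, and the class ratios were not adjusted for it. Neutrophils of the UUO samples held 5310 ± 375 UMIs (SD of sample medians, n = 2) against 2036 ± 508 (n = 4) in Control, a 2.67-fold rise (limma adjusted p 0.0105 over 19 classes). Macrophages rose 2.0-fold, from 1458 ± 230 (n = 5) to 2894 ± 184 UMIs (n = 2, adjusted p 0.0132). Among the 19 classes, genes detected per cell rose in neutrophils, 2.14-fold (adjusted p 0.0290). In Th17 cells the UMI ratio was 1.57, in CD4 T cells 1.18 and in PT cells 1.56, none of which passed. The calls rested on both UUO samples: without UUO 1 or without UUO 2 limma called 0 classes (UMIs, 4 and 2 at an unadjusted p under 0.05; genes, 3 and 2), with neutrophil UMIs 2.81-fold and 2.54-fold and macrophage UMIs 1.92-fold and 2.10-fold higher, and without Control 5 it called 8 classes higher in UMIs and 6 in genes. Without Control 4 genes were called higher in 2 classes. Without Control 6 genes in neutrophils were not called (2.28-fold). With immune cells at or above 10% mitochondrial UMIs left out, neutrophils were not called in UMIs (1.73-fold) and macrophages were 3.32-fold higher. The call in genes then passed from neutrophils (1.49-fold, not called) to macrophages (2.21-fold). Among the libraries over 10000 cells neutrophils held 2.61-fold more UMIs and macrophages, not called there, 1.97-fold more. Neutrophils and macrophages were named here after their values were seen.

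Over all cells, sample medians averaged 2540 ± 61.9 UMIs in UUO (SD, n = 2) and 1793 ± 665 in Control (n = 5), a ratio of 1.48 (exact permutation p = 0.238). Genes detected per cell were 1034 ± 5.66 and 798 ± 192 (exact p = 0.286). Mitochondrial UMIs were 12.6% ± 1.13 and 11.9% ± 3.66 (exact p = 0.905). Limma called 0 of 19 classes in mitochondrial percentage, and 0 had an unadjusted p under 0.05. Among the libraries over 10000 cells the UUO to Control log2 ratio of UMIs was 0.17 and that of genes 0.16, and the mitochondrial percentage differed by -2.95 points.

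The authors' embedding, which covers every cell outside PT, was used to ask whether cells of a class lay in another place in UUO. The design could not pass this test after adjustment: only 8 of the 18 classes had enough samples for an exact permutation p under 0.05, and the lowest adjusted p within reach was 0.106. The lowest found was 0.286. At an unadjusted exact p under 0.05 there were 3 classes, CD4 T, ALOH and Macro, each at the smallest value of 0.0476. The CD4 T groups lay 0.311 embedding units apart, against a median of 0.106 over all splits of the samples, and the Macro groups 0.152 against 0.0651. For Th17 and Treg, with 3 Control samples of at least 20 cells, the exact p was 0.30 and 1.0, where the smallest possible was 0.10.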

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

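All tests of explanations in this part were chosen after the results were seen. Among the 5 Control samples as counted, 22 of 62 sets of values had 1 sample far from the other 4. Chance alone would give about 3.1 only if the values were normally spread. They were raw percentages and medians, and all 22 samples lay on the high side, as skewed values also would. The excess is therefore no result in itself. The sets overlap, since a class share of all cells and of a compartment move together. UUO has 2 samples and was not examined in this way.

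The pooled Controls 3 and 4 stood apart in lymphoid cells, at 10.98% of all cells against 2.69% to 4.86% in the other Control samples. Of all cells they held 2.72% Treg (others 0.0777% to 0.306%), 1.67% CD8 T (others 0.109% to 0.278%), 2.06% NK (others 0.295% to 0.395%), 1.67% NKT (others 0.187% to 0.402%) and 0.805% Th17 (others 0.168% to 0.260%). Within immune cells they held 21.5% Treg (others 1.78% to 4.65%), 13.2% CD8 T (others 2.47% to 3.95%) and 16.3% NK (others 4.35% to 7.62%). A-IC made up 3.69% of their cells and 4.47% of their tubular cells, and Trans IC 2.30% and 2.79%.

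Treg, CD8 T, NK and NKT together were 64.8% of immune cells in Control 3 and 63.9% in Control 4, against 15.3% to 22.6% in the other Control samples and 29.8% and 34.2% in UUO. A swap with the UUO samples is argued against by the tubule, since 44.4% of tubular cells in Control 3 lay outside PT and at most 10.7% in UUO. Shallow libraries are argued against by Controls 1 and 2, of similar UMIs per cell, which had at most 16.1%. Immune cells rich in mitochondrial transcripts are argued against too, because the lowest share in Controls 3 and 4 was 66.5% with those cells left out. A different preparation or a different animal may remain as explanations, neither of which the labels record, and no biological explanation was tested.

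Control 5 stood apart in proliferating cells and depth. Prolif PT made up 3.27% of its cells (others 0.290% to 0.513%) and 3.52% of its tubular cells. Prolif Ly made up 0.705% of its cells (others 0.0556% to 0.154%) and 13.4% of its immune cells. Its median UMIs per cell were 2944 and its median genes 1127, against at most 1726 and 765 in the others. In Control 1, macrophages were 1.92% of cells (others 0.271% to 0.731%) and dendritic cells (DC) 0.417% (others 0.117% to 0.202%). In Control 6, monocytes were 13.3% of immune cells (others 1.78% to 4.27%).

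Cells of immune classes with at least 10% mitochondrial UMIs, a level that 50.4% to 76.2% of tubular cells reached in each sample, were 43.7% of immune cells in Control 5 and 26.5% in Control 6, against 4.98% to 8.19% in Controls 1 to 4 and 5.27% and 11.3% in UUO. In Control 5 they included 156 of 201 neutrophils, 88 of 114 Prolif Ly and 27 of 37 Treg. Against other neutrophils of Control 5 such neutrophils had a median log2 UMI ratio of -1.11 (-1.20 to -0.994), bootstrap 95% interval in brackets, which argues against doublets of an immune and a tubular cell, and a gene ratio of -1.09 (-1.18 to -1.01), as damaged cells may have. In the other immune classes of Control 5 these ratios cannot tell doublets from damage. The intervals of the UMI ratio, 0.116 (-0.0110 to 0.215), and the gene ratio, -0.0691 (-0.193 to 0.0375), include 0. UMI ratios were 0.507 (0.0295 to 1.19) in Treg and -0.111 (-0.427 to 0.0969) in Prolif Ly, and gene ratios -0.203 (-0.410 to 0.195) and -0.243 (-0.501 to 0.0186). For all these ratios the bootstrap redrew only the cells at or above 10% and held the median of the comparison cells fixed. The intervals may therefore be too narrow, as in Treg, where 27 of 37 cells lay at or above 10% and few were left to compare with. Median mitochondrial shares in Control 5 were 30.3% in Treg and 29.6% in Prolif Ly, against 14.1% in tubular cells and 11.3% in PT cells alone. In DCT, CD PC and CNT cells of Control 5 they were 23.3%, 24.4% and 26.7%. A doublet's share lies between those of its parts, so this argues against doublets with typical PT cells in Treg and Prolif Ly. Doublets with distal or collecting duct cells of a share above their class median stay open. The Treg UMI ratio lay above 0, as doublets might give, but rested on few comparison cells, so Treg stay open. In Control 6 the UMI ratio outside neutrophils was 0.220 (0.109 to 0.402), as doublets or added tubular RNA might give, and damage there (gene ratio 0.0509, -0.0278 to 0.122) and either cause in its neutrophils (UMIs 0.357, -0.243 to 0.597, genes 0.219, -0.269 to 0.367) stay open, with a difference between preparations, and no biological explanation was tested.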

How the results depend on the processing

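The pooling of Controls 3 and 4, and the alternatives with Controls 3 and 4 or Controls 5 and 6 left out, with immune cells under 10% mitochondrial UMIs, with the libraries over 10000 cells or with PT left out of the denominator were chosen after the results were seen. With 8 separate samples, as first planned, limma called 7 classes higher and 9 lower among all cells (Neutro and A-IC added), 0 and 0 among immune and 1 and 7 among tubular cells. Of 23 alternatives, Th17 was called higher among all cells in 22, CD8 effector in 21, Baso and CD4 T in 20 each, CD8 T in 18 and Treg in 17. CNT, CD PC, DCT and B-IC were called lower in 21 each and Endo in 13. Not all of these could differ from the main fit. No minimum class size left it unchanged, and leaving out Control 3 or Control 4 only trimmed the pooled sample. Exact permutation per class could hardly pass after adjustment, whatever the data. Compartment differences had the same sign in every alternative run.

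Among all cells, edgeR with sample totals gave 5 lower and the libraries over 10000 cells 5 lower, and exact permutation per class 0 and 0. Among immune cells, sample weights gave 1 higher and 1 lower, the libraries over 10000 cells 4 and 2, and leaving out Controls 3 and 4 gave 4 and 1. Among tubular cells, the count of higher classes was 0 with edgeR and sample totals, 2 with TMM and 2 with centred log-ratios, 0 with the libraries over 10000 cells, and 0 (with 0 lower) under exact permutation; lower classes were 1 with TMM and 2 with PT out of the denominator. Limma over compartments took the unchanged differences of -2.37 (endothelium), 2.30 (lymphoid), -1.42 (tubular) and 2.03 (immune) past 0.05. Genes per cell passed as a mean over class medians (0.39 log2, exact p 0.0476). UMIs were higher in 1 class with immune cells under 10% mitochondrial UMIs and in 1 with the libraries over 10000 cells, where mitochondrial percentage was lower in 2 (Treg and Profibrotic Tubules). The cause was not tested unless named.

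Reversed signs were all of differences that did not pass, except ALOH. Mitochondrial percentage was -0.427 points as a mean over cells, -1.83 over class medians, -2.95 in the libraries over 10000 cells, -0.0311 without Control 1 and -0.0418 without UUO 1. PT among all cells was -0.00647 with TMM; Prolif PT was 0.0308 without Control 5 and 0.0930 without Controls 5 and 6 (down to -1.01 without another sample). Among tubular cells ALOH was 0.106 with TMM and 0.152 with PT out of the denominator. Prolif PT there was 1.90 with TMM, 1.5 with centred log-ratios, 2.12 with PT out, 0.250 without Control 5, 0.0180 without UUO 2 and 0.291 without Controls 5 and 6 (down to -0.663 without another sample).

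Leaving out each sample in turn gave 2 to 7 higher and 0 to 9 lower classes among all cells, 0 and 0 among immune cells, and 0 to 1 higher and 0 to 7 lower among tubular cells, a lone UUO sample being assumed to vary like the Controls. Log2 odds differences ran 1.57 to 2.50 (immune), 1.86 to 2.75 (lymphoid), 0.71 to 1.43 (myeloid), -3.25 to -1.49 (endothelium), -1.92 to -0.93 (tubular), -2.11 to -0.37 (podocytes). UMIs ran 0.47 to 0.76, genes 0.32 to 0.53 (log2), and mitochondrial percentage -0.0418 to 2.14 points. By class, 0 to 8 classes were called higher in UMIs and 0 to 6 in genes, with the most without Control 5, and 0 in mitochondrial percentage.

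Control and UUO share the numbers 1 and 2, and no label says that a number pairs samples. For want of a label the numbers were not taken as pairs. Deviations from the group means correlated at -0.248 for number 1 and -0.00370 for number 2. The 2 UUO samples deviate from their mean as mirror images, so these correlations cannot decide the question. With the number as a block, limma called 5 and 6 classes among all cells, 3 and 4 among immune cells (NKT at 0.297) and 0 and 0 among tubular cells (Prolif PT at 0.0761), and UMIs higher in 6 of 9 classes with medians in all samples, 1 without the block. Only numbers 1 and 2 occur in both groups. This fit therefore compares Controls 1 and 2, both small libraries, with the UUO samples, and the other Controls add nothing to it. In simulated data of this size a class changed by 2 log2 units was called in 16.8% of cases, and 0 cells of a class in the smallest sample allow a share of up to 0.133%.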

Other observations

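The 4 ratios and the tests of explanations in this part were chosen after the class shares were seen, although the minimum of 1000 UMIs was itself planned. Intercalated cells are the acid-base regulating cells of the collecting duct. A-IC were 72.5% ± 2.11 (SD, n = 2) of A-IC plus B-IC in UUO and 46.7% ± 11.2 (n = 5) in Control. Both UUO samples, at 71.0% and 73.9%, lay above every Control sample (highest as counted 60.7%), and the exact permutation p was 0.0476, the smallest possible, or 0.190 after adjustment over the 4 ratios tested. UUO 1 held 62 and UUO 2 119 of these cells. This ratio was picked because the shares of both classes had been seen, so its p restates them and is no separate test.

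The other 3 ratios did not reach p of 0.05, and 2 of them rested on the pooled Controls 3 and 4. CD PC were 24.1% ± 7.25 of CD PC plus the 3 intercalated classes in UUO and 39.3% ± 13.6 in Control (exact p = 0.286, n = 2 and 5). The pooled sample held 16.5%, and the other 4 Control samples 40.3% to 53.0%, above both UUO samples, at 18.9% and 29.2%. Without the pooled sample the exact p was 0.0667, the smallest that 4 against 2 samples allow. Th17 were 22.3% ± 0.719 of CD4 T, Th17 and Treg together in UUO and 15.9% ± 4.38 in Control (exact p = 0.0952, or 0.133 without the pooled sample). Treg were 50.5% ± 3.46 of Treg plus Th17 in UUO and 54.4% ± 16.9 in Control (exact p = 0.667). The pooled sample held 77.2%, and without it the Control mean was 48.7% ± 12.9 (n = 4), below UUO (exact p = 0.933).

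Among tubular cells, PT rose and 6 classes of the loop, distal tubule and collecting duct fell, but with PT out of the denominator only CNT and B-IC were lower, and ALOH had the other sign (0.15). Cells of low UMI count kept in 1 group are argued against, since 7 classes were lower among tubular cells with at least 1000 UMIs. Distal cells that carry the name PT in UUO could give the same result. Median mitochondrial percentage of PT cells differed by 4.05 points (limma adjusted p 0.887), but this measure cannot decide the question. Distal classes had no fixed place relative to PT. The CNT median was 10.09% against 15.86% for PT in UUO 1, and 20.66% against 15.98% in UUO 2. In each UUO sample CD PC lay above PT and DCT below it. A PT difference of either sign could therefore neither show nor exclude such cells. Gene counts were not analysed here, so this explanation stays open. Loss of distal cells through obstruction, or a poorer release of them from obstructed tissue, also stays open and was not tested.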
